A study of Canis lupus familiaris with 25 samples.

How the data were processed

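Total RNA from carcinomas and non-neoplastic mammary glands of dogs was labelled with biotin and hybridised to Affymetrix canine arrays, 1 array per specimen, per the labels' protocols. The deposited labels tie each specimen to a numbered dog, so that the arrays of 11 dogs form pairs and each dog is 1 replicate. The authors deposited 1 normalized value per probe set and array on a log2 scale. Partek, GCRMA and RMA are named in the submitters' processing notes, without versions or the role of each, and the annotation used by the authors is not given in the sources used here. The deposited log2 values run from 0.86 to 16.66 and crowd near log2 2 at the low end, so that a fold against a mean below log2 4 is uncertain. No scan dates were used here, and scanner files were not analysed here.

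Gene names came from the platform annotation, which lists 29703 probe sets. The Entrez IDs of 27690 of these were found in a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, which changed 0 symbols, and 439 probe sets with several symbols were never named. Of the 21553 tested probe sets 16261 named 1 gene, 255 several and 5037 none. A gene was represented by the tested probe set with the highest mean over all 25 arrays, which gave 8885 genes.

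Choices of test, filter, gene lists and named genes were made before the data were examined, except where stated. The 111 control probe sets were left out, and a probe set was tested if it exceeded log2 4 in at least 6 of the 22 paired arrays. Tumour and gland were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with the dog as a fixed block. Tests were 2-sided, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. No normalization was added. The paired differences are given as mean ± SD over 11 dogs. Survival and tumour size were tested as slopes in the tumours, for probe sets above log2 4 in at least 4 arrays, and ERBB2 was compared between HER-2 labels by an exact permutation test of the means, with the 1-sided p doubled. The p by absolute size was added after the data were seen.

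Lists of genes were fixed for 27 pathways and cell types that the tissue could hold: mitosis, DNA replication, DNA repair, matrix proteases, stromal collagens, basement membrane and integrins, junctions, epithelial-mesenchymal transition, endothelium, luminal epithelium, milk, basal and myoepithelial cells, adipocytes, T and NK cells, B and plasma cells, macrophages and neutrophils, mast cells, interferon response, receptor tyrosine kinases, glycolysis and hypoxia, unfolded protein response, immediate early genes, skeletal muscle, epidermis, erythrocytes, nerve, and lymphatic vessels. The 24 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and again with a correlation estimated per list. KIT, ERBB3 and FLT4 each stood on 2 lists. Fry, which asks whether a list moves on balance in 1 direction, and an exact sign-flip test of list means over the dogs were set beside it, the latter chosen after the data were seen.

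The named genes were set by a rule: the 10 largest rises and 10 largest falls among genes called with the same sign in all 11 dogs, per list the 2 called members with the largest change and the largest called change in the opposite direction (or the 2 smallest p where none was called), ERBB2, ESR1, PGR and MKI67, and the 2 smallest p of each trend. A gene that the rule names among the DNA repair genes is not reported here. Other genes are named only in the closing observations, as chosen after their values were seen.

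The labels pair the tissues by dog. After removal of the tissue means, tumour and gland of the same dog correlated at 0.119 to 0.456 in all 11 dogs, against a median of -0.064 between dogs, and the own gland correlated best in 5 of 11. In a check of dog identity added after the data were seen, 150 probe sets with dog-specific levels were picked without the dog under test, and the tumour then matched its own gland best in 11 of 11 dogs, at correlations of 0.576 to 0.887 against at most 0.513 for another gland.

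The paired test was tested on simulated arrays with the means and spread of the 21553 probe sets. With 100 probe sets changed at each size, it recovered 62% of changes of 1 and 88% of changes of 2 on the log2 scale. Of its calls 5.06% were false, and it made 0 calls where nothing was changed. In the data 6128 probe sets were called, far more than were changed here, so these recovery rates need not carry over. In the simulated survival trend over 21261 probe sets, with 100 changed at each slope, 38% of slopes of 0.25 and 84% of slopes of 0.5 per month were recovered. There were 13 false calls beside these. In both simulations the noise was drawn independently for each probe set. Camera with the preset correlation gave an unadjusted p under 0.05 in 6% of 200 simulated null lists. Those lists held uncorrelated genes, whereas the correlation estimated in the data reached 0.768 for the mitosis list, so that the 6% does not carry over to the real lists.

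Alternatives covered the dog block, the unpaired arrays, the filter, a second normalization, array weights, the variance trend, an exact signed-rank test, the unexplained title suffix of 9 tumours, an adipocyte covariate and leaving out each dog. Added after the data were seen were the 5 dogs without muscle signal in the gland, a muscle covariate and a covariate for the actin 3' to 5' ratio. Plots were drawn with matplotlib 3.10.9.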

Results

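Gene expression was measured on 25 Affymetrix canine arrays in dogs with simple mammary carcinoma and lymph node metastases. The arrays covered 13 carcinomas and 12 specimens of non-neoplastic mammary gland, and 11 dogs gave both tissues. Specimens had been macrodissected for a high content of tumour or gland epithelium. Each array gave 1 log2 value for each of 43035 probe sets, with array medians from 3.56 to 3.77, and between 47.5% and 48.8% of probe sets above log2 4. No pair of arrays held identical values. The number of dogs limits the precision of every comparison. The unpaired arrays were the tumours of dogs 1 and 9 and the gland of dog 8.

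The main comparison asked which genes differ between the carcinoma and the gland of the same dog. In the carcinomas 30 of 31 mitosis genes, 28 of 29 DNA replication genes and 16 of 19 glycolysis and hypoxia genes were called higher, and 13 of 15 basal and myoepithelial, 13 of 21 endothelial, 8 of 15 adipocyte, 5 of 10 milk and 4 of 5 mast cell genes lower. These lists passed camera with a preset correlation, but no list passed with an estimated one (smallest adjusted p = 0.0787 with an estimated correlation). The largest rise shared by all 11 dogs was that of CA9, a carbonic anhydrase induced by hypoxia, at 4.85 ± 2.68 on the log2 scale (SD over 11 dogs), with all 11 glands below log2 4. With the adipocyte covariate CA9 differed by 2.08 (adjusted p = 0.689), less than ISG20 at 5.83 (adjusted p = 0.335) or TK1 at 4.30 (adjusted p = 0.403). That covariate correlated at -0.926 with tissue within dogs, so these values are imprecise and do not rank the genes by dependence on fat. The largest fall shared by all 11 dogs was that of LALBA, the milk protein alpha-lactalbumin, which decreased by 7.14 ± 3.45, with 6 of 11 tumours below log2 4. Limma called 6128 of 21553 tested probe sets at an adjusted p of 0.05, 3735 higher and 2393 lower in tumour, and 2570 of these calls were at least 2-fold (1235 higher, 1335 lower). At the level of genes, 2628 of 8885 were called, 1638 higher and 990 lower. Of the called genes, 758 differed in the same direction in all 11 dogs (8.53% of the genes tested), 504 higher and 254 lower. The median difference over all genes tested was 0.10. With each array centred on its median, 990 of the 990 lower calls but 1357 of the 1638 higher calls were kept. A second quantile normalization kept 986 and 1344, so that part of the excess of rises depends on the normalization. The number of genes called, tumour versus gland, was 0 with a covariate for adipocyte genes and 428 with one for skeletal muscle genes, and the 5 dogs without muscle signal in the gland gave 258. The adipocyte covariate raised the median standard error from 0.20 to 0.53, so the 0 calls do not show that fat accounts for the differences. Random sets of 5 dogs gave a median of 184.5 genes, so the small number of dogs may account for the 258.

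Besides CA9, the 10 largest rises shared by all dogs held the replication genes TK1 (4.15 ± 1.91), RRM2 (3.82 ± 2.03) and ORC6 (3.75 ± 1.56), and the mitosis genes PTTG1 (4.00 ± 1.99), NCAPG (3.92 ± 2.27), TOP2A (3.78 ± 1.92) and PRC1 (3.70 ± 2.12). The others were ISG20, an interferon-induced exonuclease (3.99 ± 1.89), and ESM1, a proteoglycan secreted by endothelial cells (3.97 ± 1.80). Their adjusted p lay between 0.000188 and 0.000897. CA9, ISG20, ESM1 and PRC1 averaged below log2 4 in the gland, and RBP7 in the tumour, where values lie near the floor and the size of a difference is uncertain. The same holds for LALBA, BTN1A1 and ALPL, each below log2 4 in 6 of 11 tumours. Of the genes named further on, CMA1 and S100B lay below log2 4 in 7 of 11 tumours, CTLA4 in 6 of 11 tumours and 10 of 11 glands, and RSAD2 in 10, CXCL13 in 9, MMP11 in 8 and MMP13 and CDH3 in 6 of 11 glands. Besides LALBA, the largest falls were those of the casein CSN2, which decreased by 6.75 ± 3.27, and of RBP7, a retinol-binding protein, which decreased by 6.32 ± 1.14 with the smallest adjusted p of the 20 genes (9.37e-07). CES1, a carboxylesterase, fell by 5.71 ± 3.90, CLEC3B (tetranectin) by 5.56 ± 2.85, BCHE (butyrylcholinesterase) by 5.35 ± 3.57 and HEPACAM2 by 4.97 ± 2.30. BTN1A1, a protein of the milk fat globule, fell by 4.54 ± 2.08, FABP4, the fatty acid carrier of adipocytes, by 4.45 ± 2.46, and the alkaline phosphatase ALPL by 4.29 ± 2.07. Of the 4919 genes with several tested probe sets, 5 had a called probe set in the direction opposite to that of their representative.

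**Figure D1:**
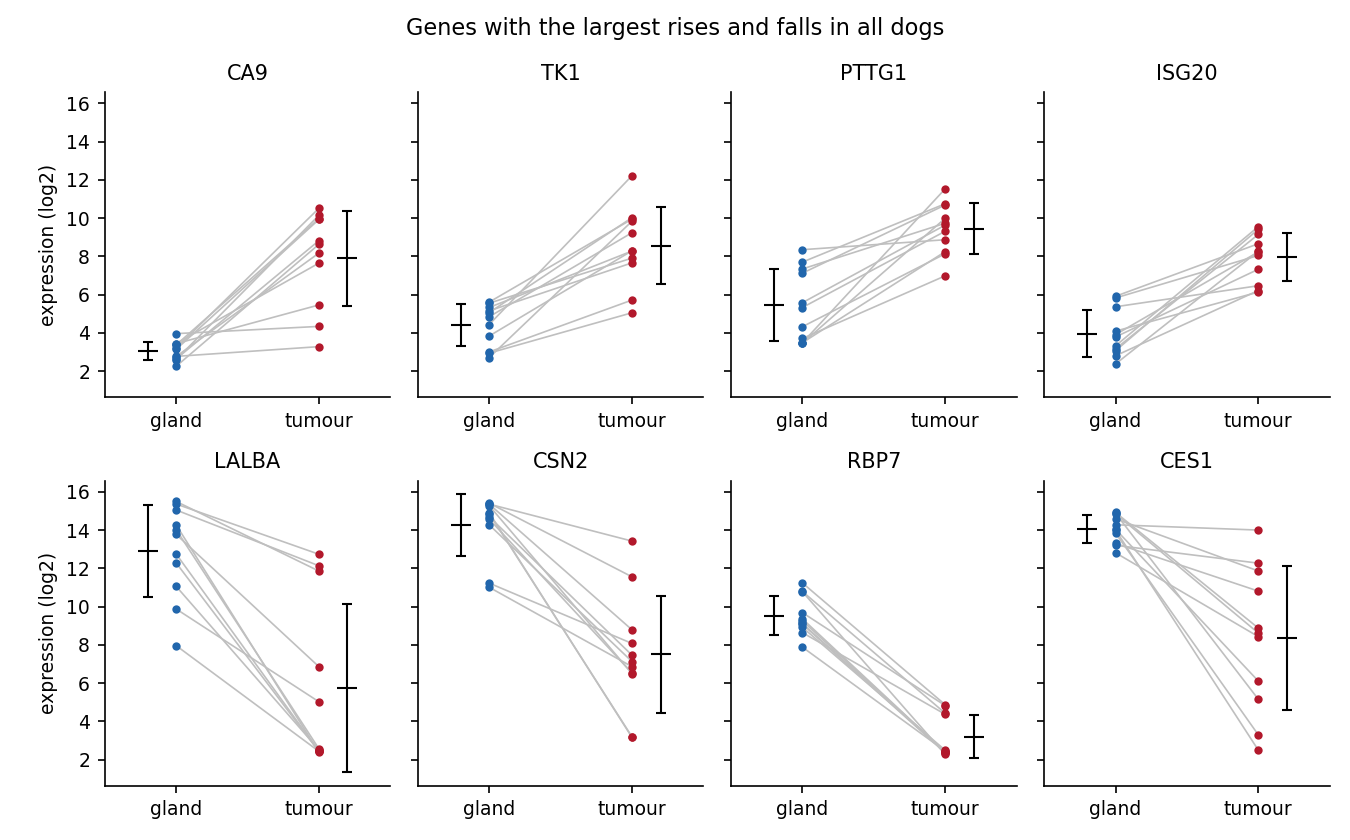
Expression (log2) of the 4 genes with the largest rises and the 4 with the largest falls shared by all 11 dogs. Points are arrays, grey lines join the gland (blue) and the carcinoma (red) of 1 dog, and bars give mean ± SD (n = 11); every line rises for CA9, TK1, PTTG1 and ISG20 and falls for LALBA, CSN2, RBP7 and CES1.

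The means of the mitosis and DNA replication lists moved furthest upward of the 24 tested lists. Of 31 tested mitosis genes, 30 rose, among them PTTG1 (securin) and TOP2A (topoisomerase II alpha), and the list mean was higher by 2.87 ± 1.54 in 11 of 11 dogs. Of 29 DNA replication genes, 28 rose, with TK1 (thymidine kinase) and RRM2 (a ribonucleotide reductase subunit) at the top and a list mean of 1.85 ± 0.97, higher in 11 of 11 dogs. Of 18 DNA repair genes, 12 rose, with a list mean of 0.87 ± 0.57 that was higher in 10 of 11 dogs. FANCD2, of the Fanconi anaemia pathway, rose by 1.77 ± 1.21. The counts adjusted over the list alone were 30, 28 and 14. Camera with a preset correlation called all 3 lists (adjusted p = 1.94e-15, 1.15e-13 and 0.000200), and none with an estimated correlation (adjusted p = 0.176, 0.176 and 0.241 with an estimated correlation).

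Glycolysis and hypoxia genes rose in 16 of 19 cases, with a list mean of 1.35 ± 0.54, higher in 11 of 11 dogs. CA9 led the list, followed by EGLN3, a prolyl hydroxylase that is itself induced by hypoxia (2.60 ± 1.87, 6.08-fold). The list of the unfolded protein response and chaperones shifted less, with 13 of 23 genes higher, a list mean of 0.45 ± 0.24 and a higher mean in 11 of 11 dogs. HSPH1, a heat shock protein, rose by 1.36 ± 0.65 and CALR (calreticulin) by 0.76 ± 0.48. Adjusted over the list alone, 16 and 15 genes passed. Camera gave adjusted p = 6.97e-09 and 0.000179 for these lists with the preset correlation, and adjusted p = 0.0962 and 0.176 with an estimated correlation.

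Genes of immune cells mostly did not pass the test. In the interferon and antigen presentation list 4 of 21 genes rose, including RSAD2 (viperin, 2.47 ± 1.91) and the chemokine CXCL10 (2.25 ± 2.55), with 1 gene passing when adjusted over the list alone. The list mean was higher by 0.73 ± 0.94 in 9 of 11 dogs. Camera called this list (adjusted p = 0.0157), but not without dog 3 (0.0623), not by fry (0.0721), not with a covariate for the actin 3' to 5' ratio (0.225) and not with an estimated correlation (adjusted p = 0.614 with an estimated correlation). Of 21 macrophage and neutrophil genes 1 rose, the monocyte chemoattractant CCL2 (1.66 ± 1.37, 3.16-fold), which also passed when adjusted over the list alone. Of 14 T and NK cell genes 1 rose, the inhibitory receptor CTLA4 (1.39 ± 1.78, adjusted p = 0.0486), and 0 passed when adjusted over the list alone. Of 6 B and plasma cell genes 0 were called in either way of adjusting: PRDM1, a plasma cell transcription factor, differed by 1.24 ± 1.73 (adjusted p = 0.0645) and DERL3 by 0.92 ± 2.02 (adjusted p = 0.219). Camera called none of these 3 cell lists (adjusted p = 0.194, 0.421 and 0.421). The macrophage list passed without dog 12 (0.0358). CXCL10 lost its call without dog 6, 7 or 11 (adjusted p from 0.0509 to 0.0586). CTLA4 lost its call without dog 2, 3, 6, 7, 10, 11 or 14 (adjusted p from 0.0683 to 0.0985), and PRDM1 gained one without dog 12 or 13 (adjusted p = 0.0257 and 0.0391).

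Called genes of the milk, luminal and basal lists all fell. Of 10 milk and lactation genes 5 fell, led by LALBA and CSN2, and the list mean was lower in 11 of 11 dogs, at -2.31 ± 0.75. Of 17 genes of luminal epithelium and hormone receptors 9 fell, with a list mean of -1.43 ± 0.69 that was lower in 10 of 11 dogs. GATA3, a transcription factor of luminal cells, fell by 3.49 ± 2.89 (11.2-fold) and PRLR, the prolactin receptor, by 3.22 ± 1.63 (10 of 11 tumours below log2 4). Of 15 basal and myoepithelial genes 13 fell, including the smooth muscle myosin MYH11, which decreased by 4.24 ± 1.92 (18.9-fold), and the keratin KRT17, which decreased by 3.87 ± 2.87. The mean of the basal list was lower in 11 of 11 dogs, at -1.95 ± 0.88. Adjusted over the list alone, 6, 10 and 13 genes passed. Camera called the milk, luminal and basal lists (adjusted p = 0.000304, 2.66e-05 and 7.58e-10) and none with an estimated correlation (adjusted p = 0.0787, 0.0795 and 0.0795 with an estimated correlation).

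Of 15 adipocyte genes 8 fell, including FABP4 and the fatty acid transporter CD36, which decreased by 3.72 ± 1.09, with a list mean of -1.37 ± 0.59. Of 21 endothelial and angiogenic genes 13 fell and 1 rose, with a list mean of -1.05 ± 0.60. CLDN5, a tight junction protein of endothelium, fell by 3.98 ± 1.45 and the von Willebrand factor gene VWF by 2.36 ± 1.02, whereas VEGFA, an endothelial growth factor made by many cell types, rose by 1.16 ± 0.99. Of 5 mast cell genes 4 fell, with a list mean of -2.21 ± 1.04. Carboxypeptidase CPA3 decreased by 3.97 ± 2.69 and chymase CMA1 by 3.83 ± 1.56. Of 18 receptor tyrosine kinase and ligand genes 8 fell, with a list mean of -1.06 ± 0.62, and the growth factor IGF1 decreased by 3.17 ± 1.37 and IGF2 by 2.80 ± 3.11 (10 of 11 tumours and 4 of 11 glands below log2 4). The means of all 4 lists were lower in 11 of 11 dogs. Adjusted over the list alone, 9 adipocyte, 14 endothelial (with 1 rise), 4 mast cell and 9 receptor genes fell. Camera gave adjusted p = 7.30e-06, 2.42e-08, 0.000741 and 3.04e-05 for the 4 lists in this order, and adjusted p = 0.0787, 0.0962, 0.0962 and 0.0787 with an estimated correlation. IGF2 lost its call without dog 4, 7 or 10 (adjusted p = 0.0509, 0.0536 and 0.0574).

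**Figure D2:**
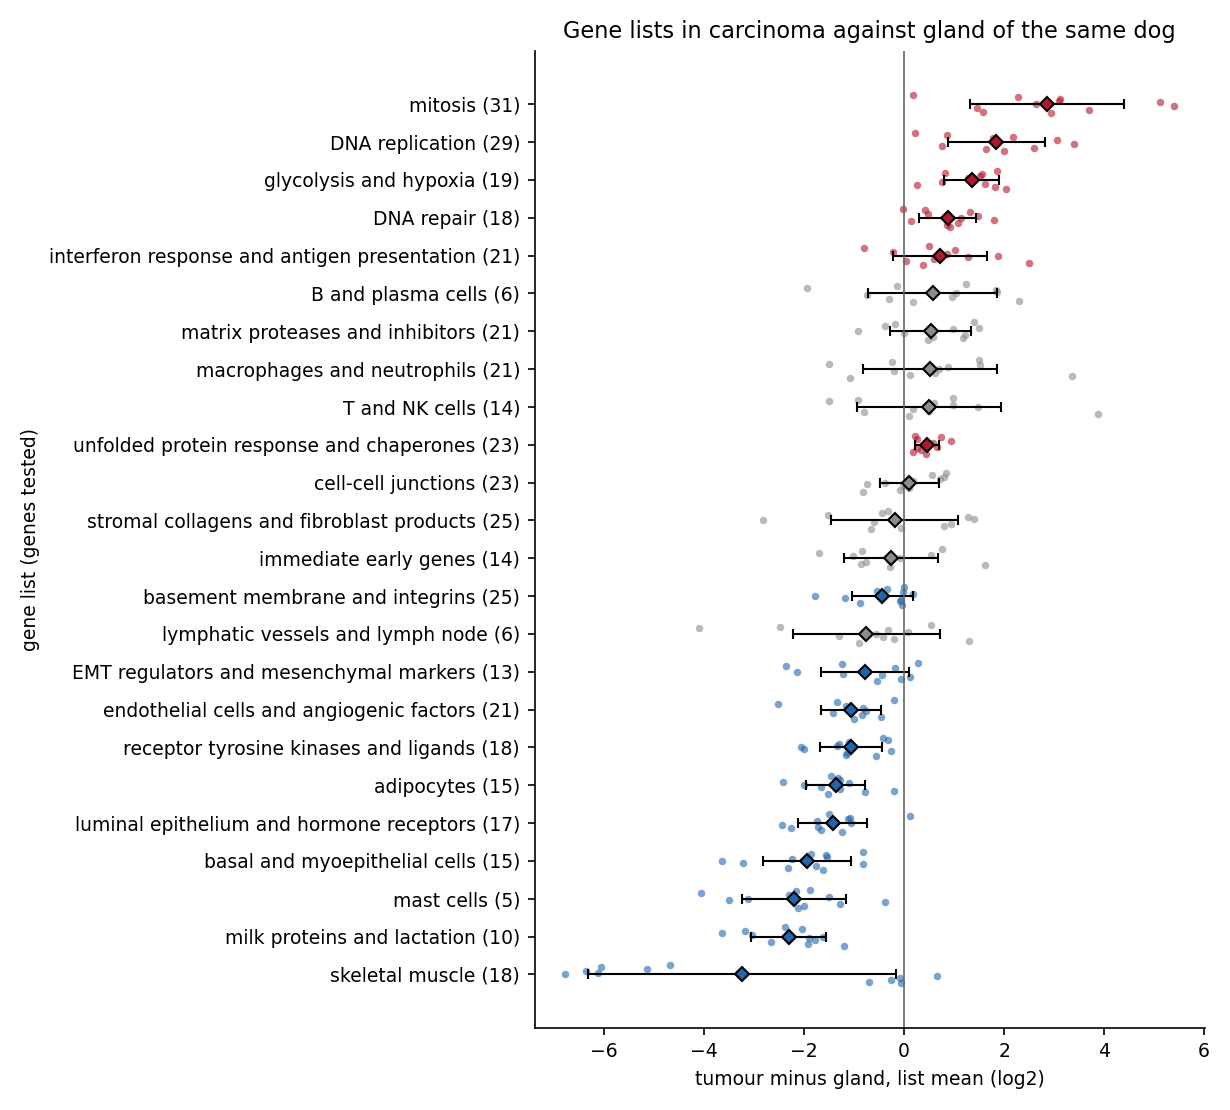
Difference between carcinoma and gland of the same dog in the mean of each of the 24 tested gene lists (log2), with the number of genes tested in brackets. Points are the 11 dogs, diamonds and bars give mean ± SD, and colour marks the 16 lists called by camera with the preset correlation (red higher, blue lower in tumour, grey not called); mitosis lies at 2.87 ± 1.54 and milk proteins at -2.31 ± 0.75.

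Called matrix and adhesion genes went both ways. Of 21 matrix protease and inhibitor genes 4 rose and 1 fell. The collagenase MMP13 rose by 4.65 ± 1.99 and MMP11, stromelysin 3, by 3.14 ± 3.01, while the aggrecanase ADAMTS5 decreased by 1.08 ± 1.24. Of 25 genes of stromal collagens and fibroblast products 4 fell and 1 rose. COL14A1 decreased by 2.60 ± 1.55 and the receptor PDGFRB by 1.73 ± 1.18, and the collagen cross-linking enzyme LOXL2 rose by 1.48 ± 1.33. Of 23 junction genes 2 rose and 2 fell. The claudin CLDN8 decreased by 1.67 ± 1.34, and P-cadherin, CDH3, rose by 1.66 ± 1.45 and the nectin NECTIN2 by 0.72 ± 0.81. These 3 lists were not called by camera (adjusted p = 0.759, 0.117 and 0.939), with mean differences of 0.53 ± 0.81, -0.18 ± 1.27 and 0.11 ± 0.59. The junction list differed by 0.46 ± 0.48 in the 6 dogs with skeletal muscle signal in the gland and by -0.31 ± 0.43 in the other 5, a contrast that was not tested, and camera gave a lower level with the muscle covariate (adjusted p = 0.0866). Adjusted over the list alone, 4 protease genes rose and 1 fell, 1 stromal gene rose and 3 fell, and 1 junction gene rose and 1 fell. The stromal list passed without dog 4, 10 or 11 (adjusted p = 0.0399, 0.0289 and 0.0361).

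Of 25 basement membrane and integrin genes 5 fell, including the laminin chains LAMA3, which decreased by 2.43 ± 2.94, and LAMB2, which decreased by 1.63 ± 0.81. The list mean was lower in 10 of 11 dogs, at -0.43 ± 0.61. Of 13 regulators and markers of the epithelial-mesenchymal transition 6 fell and 1 rose, with a list mean of -0.78 ± 0.88 that was lower in 9 of 11 dogs. The TGF-beta co-receptor TGFBR3 decreased by 3.47 ± 1.65 and the transcription factor ZEB1 by 1.5 ± 1.01, whereas the kinase receptor TGFBR1 rose by 1.09 ± 0.55. Adjusted over the list alone the counts were the same, at 5 falls for the first list and 6 falls with 1 rise for the second. Camera called both lists (adjusted p = 0.0157 and 0.00239), neither with an estimated correlation (adjusted p = 0.422 and 0.408 with an estimated correlation), and the first not without dog 7 (0.0594) or by fry (0.136). The second was not called by fry (0.0506) or with a skeletal muscle covariate (0.0866). ADAMTS5 lost its call without dog 2, 6, 7, 10, 12, 13 or 14 (adjusted p from 0.0563 to 0.0688), NECTIN2 without dog 3, 4, 6, 7, 10, 11 or 12 (0.0567 to 0.0803) and LAMA3 without dog 3, 4, 6, 7 or 10 (0.0558 to 0.0716). Without the dog as a block, the calls of ADAMTS5 (adjusted p = 0.105), CLDN8 (0.0507), CDH3 (0.0563) and NECTIN2 (0.309) were lost.

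Of 18 skeletal muscle genes 13 fell, including the myosin light chains MYL1, which decreased by 5.29 ± 5.05, and MYL2, which decreased by 5.21 ± 5.16, each below log2 4 in 11 of 11 tumours and 5 glands. The muscle list mean lay between 8.79 and 10.17 in the glands of dogs 7 and 10 to 14, and between 3.38 and 4.74 in the other 19 arrays. The list differed by -5.86 ± 0.79 in these 6 dogs and by -0.09 ± 0.49 in the other 5, set apart by their low gland level, where camera gave an adjusted p of 0.201 (0.195 with an estimated correlation in all 11 dogs, against 4.78e-08 with the preset one). Of 4 nerve and Schwann cell genes, too few for the list test, 2 fell: S100B, a calcium-binding protein of glia and other cells, decreased by 4.02 ± 2.92 and the myelin protein PMP22 by 1.44 ± 1.31. Of 6 lymphatic and lymph node genes 2 fell and 1 rose. The lymphatic chemokine CCL21 decreased by 3.09 ± 1.98 and the lymphatic receptor LYVE1 by 2.64 ± 1.67, and the B cell chemokine CXCL13 rose by 3.15 ± 3.53. Of 14 immediate early genes 3 fell, including the transcription factor KLF4, which decreased by 1.24 ± 1.38, and the phosphatase DUSP1, which decreased by 1.12 ± 1.30. Adjusted over the list alone, 16 muscle, 2 nerve, 3 lymphatic (with 1 rise) and 3 immediate early genes fell. Camera did not call the lymphatic list (adjusted p = 0.0618) or the immediate early list (0.103), but the former passed without dog 3, 4, 5, 10 or 11 (0.0367 to 0.0483), by fry (0.0293), with the actin covariate (0.0287) and with no filter on low values (0.0235). The latter passed without dog 3 or 11 (0.0114 and 0.0433) and with the actin (0.0108) and adipocyte (0.0286) covariates. CXCL13 lost its call without dog 3, 6, 7, 10 or 11 (adjusted p from 0.0502 to 0.0576), KLF4 without dog 10 (0.0577) and DUSP1 without dog 2, 4, 6, 10 or 12 (0.0570 to 0.0707). No gene of the epidermis and erythrocyte lists was tested.

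**Figure D3:**
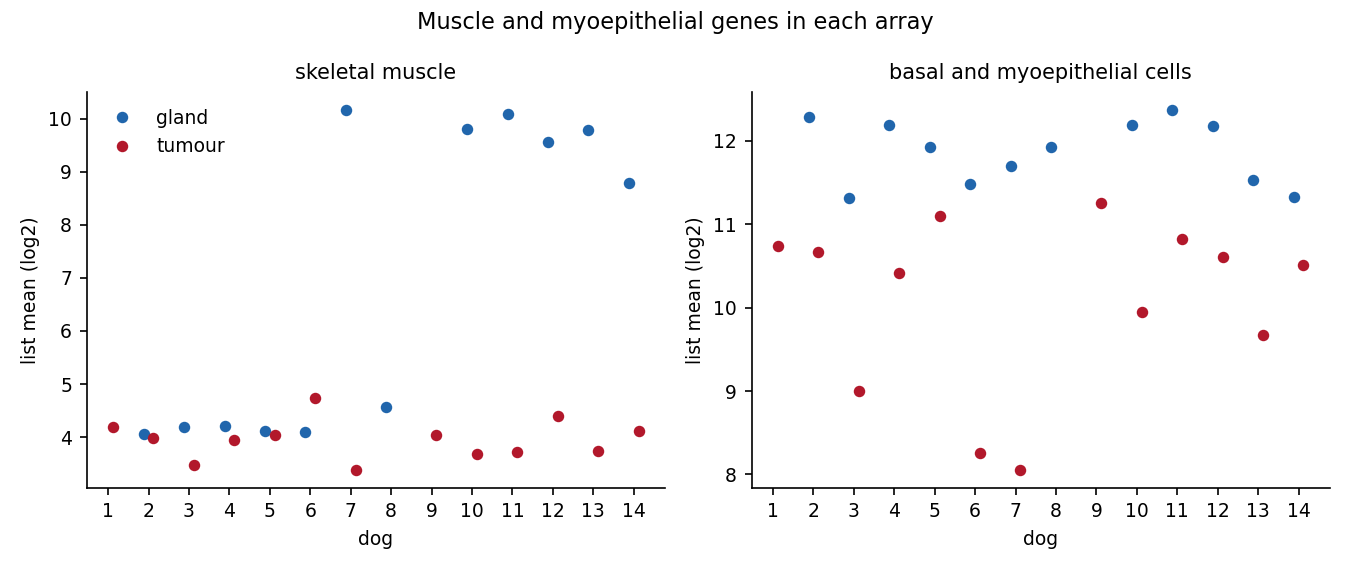
Mean expression (log2) of the 18 skeletal muscle genes (left) and the 15 basal and myoepithelial genes (right) in each gland (blue) and carcinoma (red) by dog number. The muscle list lies at 8.79 or more in the glands of 6 dogs and at 4.74 or less in all other arrays, and the basal list is lower in the carcinoma than in the gland in all 11 paired dogs.

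Of the 16 lists called by camera, 6 were higher and 10 lower in tumour, out of 24 tested. An exact 2-sided sign-flip test of each list's mean over the 11 dogs called 16 lists as well, with the smallest p it can give, 0.000977 (adjusted p = 0.00234), for 10 of them. With the adipocyte covariate camera no longer called the lists of the transition (adjusted p = 0.656), basement membrane (0.795), mast cells (0.0920), receptor tyrosine kinases (0.0894), skeletal muscle (0.729) and chaperones (0.423). The adipocyte list lost its call too (0.656). That loss was fixed by the design, because the covariate is the mean of this same list and takes up its average difference. The endothelial list stayed called (0.000219), as did the other 8 lists called without the covariate. The 3' to 5' signal ratio of the actin control probe sets, a measure of RNA integrity, was lower in tumours by 0.32 ± 0.53 on the log2 scale (exact sign-flip p = 0.0674, adjusted p = 0.135).

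The hormone and growth factor receptors used to classify mammary tumours were examined in every array. The labels give all 13 tumours as negative for oestrogen receptor alpha, 11 as positive and 2 as negative for HER-2, the receptor encoded by ERBB2. The oestrogen receptor gene ESR1 was above log2 4 in 4 of 12 glands and 0 of 13 tumours, at means of 3.37 ± 1.10 (SD, n = 12) and 2.35 ± 0.42 (SD, n = 13), and was left out of the test by the filter on low values. The progesterone receptor gene PGR decreased by 2.33 ± 2.16 (adjusted p = 0.0108), with lower values in the tumour of 9 of 11 dogs. No difference of ERBB2 between tumour and gland was called, at -0.35 ± 0.81 with lower values in 8 of 11 tumours (adjusted p = 0.278). Among tumours, ERBB2 was 6.46 ± 1.08 (SD, n = 11) with a positive HER-2 label and 4.68 ± 0.10 (SD, n = 2) with a negative one, a difference of 1.78 or 3.44-fold. Of the 78 possible splits 1 gave as large a difference in this direction (exact permutation p = 0.0256, the 1-sided p doubled, which is the smallest this gives) and 3 in either direction (exact 2-sided permutation p = 0.0385 by size). Taken as tumour minus gland, the difference between labels was 0.37, with -0.32 ± 0.84 in 10 positive dogs and -0.69 in 1 negative dog. The lowest positive tumour, at 4.82, lay close to the higher negative one, at 4.75. Among tumours whose title carried an unexplained suffix, the 8 positive ones averaged 6.22 ± 1.12 against 4.61 in the negative one, and among those without it the 3 positive ones averaged 7.11 ± 0.77 against 4.75. MKI67, the proliferation marker, had no named probe set.

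**Figure D4:**
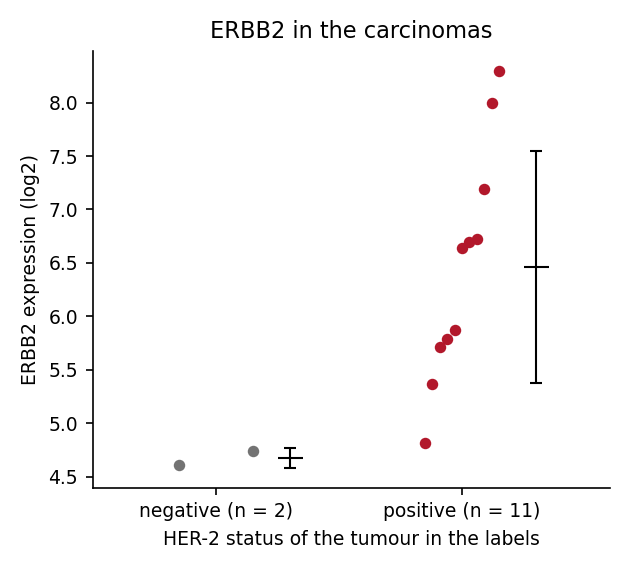
ERBB2 expression (log2) in the 13 carcinomas by the HER-2 status given in the labels. Points are tumours, and bars give mean ± SD, 4.68 ± 0.10 for the 2 negative and 6.46 ± 1.08 for the 11 positive tumours; as tumour minus gland the difference between labels was 0.37.

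Survival after surgery, from 1 to 9 months in 12 dogs, was not related to any gene at the threshold. Limma called 0 of 21261 probe sets for a trend with survival, and 523 (2.46%) had an unadjusted p under 0.05. The smallest p belonged to CTNNAL1, a catenin-like protein, with a slope of 0.34 ± 0.06 per month (SE, n = 12, adjusted p = 1.00), and to PENK, the enkephalin precursor, with 1.02 ± 0.22 (adjusted p = 1.00). Tumour size, from 0.5 to 5 cm in 13 dogs, gave 0 calls among 21434 probe sets and 2026 (9.45%) with an unadjusted p under 0.05. PTGS2, the inducible cyclooxygenase, had a slope of 1.56 ± 0.25 per cm and DSCC1, a sister chromatid cohesion factor, of -0.71 ± 0.12 per cm (SE, n = 13, adjusted p = 0.341 for both). In 9 of 100 orders of the sizes over the tumours, the real one included, as many probe sets had a p under 0.05. Slopes on the rank of survival or size also gave 0 calls.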

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

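The 5 dogs without muscle signal in the gland and the muscle and actin covariates were chosen after seeing the data. For probe sets called, tumour versus gland, for probe sets called at 2-fold or more, tumour versus gland, and for genes called, tumour versus gland, the adipocyte covariate gave 0, 0 and 0, the 5 dogs 573, 548 and 258, and the muscle covariate 966, 827 and 428. Of the 2628 genes, 2464, 2617 and 2610 kept their direction in these settings. The adipocyte covariate held 85.7% of the variance of tissue within dogs, and the median standard error rose from 0.20 to 0.53 (0.30 with muscle) while the median size of the called differences went from 0.88 to 0.83 (0.84). The difference itself fell below 0.5 times its size for 1317 of the 6128 probe sets (235 with muscle), for VEGFA from 1.16 to 0.027. The dogs with the title suffix, fewer in number, gave 4083 probe sets. No gland title carried the suffix, so in these dogs it cannot be told apart from tissue. This alternative therefore does not test an effect of the suffix. For fixed gene lists called, tumour versus gland, the adipocyte covariate gave 10, an estimated correlation 0 and fry 14. Under the adipocyte covariate CTLA4 (-0.24), MYL1 (0.018) and MYL2 (0.88) changed sign, as did MYL2 in the 5 dogs (0.018) and with the muscle covariate (0.12). The cause under the adipocyte covariate was not tested. MYL2 averaged log2 2.26 in the glands without muscle signal and 2.27 in the tumours, so in the 5 dogs its sign is that of a difference at background. The muscle covariate is the mean of a list that holds MYL2 and takes up the average fall of its members. The ERBB2 difference by HER-2 label was 0.37 as tumour minus gland, with 1 negative dog; a mean over ERBB2 probe sets was not run because only 1 names the gene. Leaving out each dog gave 4789 to 6235 probe sets, 2237 to 2821 at 2-fold or more, 2068 to 2671 genes and 15 to 19 lists. Without the dog as a block, 5002 probe sets, 2337 at 2-fold or more, 2152 genes and 16 lists were called, and 2083 of the genes were among the 2628. The other alternatives kept these 4 counts within 1.5 times. Each trend kept 0 calls under the alternatives run, with a smallest adjusted p of 0.232 to 0.973 for size. Of 1764 values of the 68 named genes, 242 lost the call, and 5 of these changed sign. Signal near the floor limits genes below log2 4.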

Other observations

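The genes of the first 2 paragraphs and the tests of the muscle list, of the gap between lists, of the adipocyte adjustment of other lists, of tumour size and of the splits for the sign-flip test were chosen after the result they bear on was seen. The condensin subunits NCAPG2 and NCAPH rose by 2.97 ± 1.59 and 2.48 ± 1.6 on the log2 scale in 11 of 11 dogs (adjusted p = 0.000652 and 0.00176). Cyclin E genes rose too, CCNE1 by 2.11 ± 1.05 in 11 dogs and CCNE2 by 2.93 ± 1.62 in 10, and so did the cyclin-dependent kinase inhibitor CDKN1A, by 1.91 ± 1.34 in 11 dogs. The sterol synthesis enzymes SQLE and CYP51A1 rose by 2.93 ± 1.07 and 1.99 ± 1.32 in 11 dogs, and MTHFD2, a mitochondrial enzyme of folate metabolism, by 3.08 ± 1.18. EZH2, the methyltransferase of the polycomb complex, rose by 1.58 ± 0.98, and DLX5, a homeobox gene, by 3.09 ± 1.28 from a gland mean below log2 4.

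Among the genes that fell in 11 of 11 dogs were 3 related lipid transporter genes, ABCA6, ABCA8 and ABCA9, which decreased by 3.64 ± 2.25, 3.32 ± 1.57 and 3.71 ± 1.29. The complement component C7 decreased by 4.27 ± 2.26 and the small proteoglycan OGN by 3.73 ± 1.47. Both the angiotensin receptor AGTR1 and the angiotensin-converting enzyme ACE fell, by 3.40 ± 1.27 and 2.89 ± 1.44, to tumour means below log2 4. CXCL12, a chemokine of stromal cells, decreased by 2.80 ± 1.59, and VEGFD, a growth factor of lymphatic vessels, by 4.03 ± 1.33.

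The gland of dog 8, which had no matching tumour, lay apart from the 11 paired glands. Its adipocyte list mean was 6.51, against 8.44 to 11.19 in the paired glands and 7.15 to 9.76 in their tumours, and its mast cell list mean was 4.18, against 5.92 to 8.69 in the paired glands. Its endothelial list was at 6.39, below the lowest paired gland at 6.90, and its milk list at 8.00, below the lowest at 9.27. Its mitosis list, at 5.18, and its basal list, at 11.93, lay within the range of the paired glands. Over all probe sets its closest array was the tumour of dog 14 (correlation 0.969), and the tumours of dogs 5 and 13 were closest to the gland of dog 5 (0.975 and 0.969). T and NK cell genes were most abundant in the tumours of dogs 3 and 7, at list means of 8.90 and 8.22, against 4.37 to 6.82 in the other 11 tumours.

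Tumour and gland were swapped within randomly chosen dogs, for 100 splits with the real assignment included. Only 1, the real one, gave as many called probe sets (6128, highest other 4565), probe sets at 2-fold or more (2570, highest other 1988) or genes (2628, highest other 1971), so that chance assignment can be excluded for these counts; each highest other came from a split that swapped 1 dog. For the 16 lists called by camera with a preset correlation, 20 of the 100 splits gave as many, up to 19, with a median of 10 over the other splits, so that chance cannot be excluded for that count. For the 16 lists called by the exact sign-flip test only 1 split, the real one, gave as many, the highest other being 14. Swapping the tissues of a dog is the same as flipping the sign of its difference. This count therefore repeats the sign-flip test and adds no separate support.

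Of 18 tested skeletal muscle genes 13 were lower in the carcinomas, and a candidate explanation is muscle tissue in part of the gland specimens. With each gene in turn left out of the choice of glands, the others picked the same 6 glands. Of the 18 left-out genes 14 were higher in each of these glands than in every other array. The other 4 (MYH2, TNNI2, CKMT2 and ATP2A1) were as high in some other array. Myosin light chain MYL1 was at 12.21 in these 6 glands and 2.51 in the other glands, and actin ACTA1 at 15.63 and 11.44. The list means lay so far apart that leaving out 1 gene could not change the choice. The count was also 14 with no gene left out, so leaving genes out is no separate check. Loss of contractile myoepithelial cells is argued against as the whole cause by the gland levels. The basal and myoepithelial list lay between 11.31 and 12.37 in the glands of all 11 paired dogs. The muscle list was at 8.79 or more in 6 of these glands and at 4.74 or less in the other 5. Of the 9 dogs whose basal list fell by over 1 on the log2 scale, 4 had a muscle list that did not. That count cannot test the loss, because the glands of these 4 dogs had no muscle signal that could fall. Dog 6 was 1 of them, with differences of -3.21 in the basal list and 0.65 in the muscle list. The 5 dogs without muscle signal in the gland gave 258 called genes, and 54 of 100 random sets of 5 dogs gave as few, so that the small number of dogs may account for the lower count. Whether these glands held muscle stays open without histology, and no other biological explanation was tested.

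The adipocyte, endothelial and mast cell list means were lower in all 11 carcinomas than in the paired glands, with 8 of 15, 13 of 21 and 4 of 5 genes called lower and 1 endothelial gene, VEGFA, higher. A smaller share of all cells other than epithelium in the tumour specimens is argued against as the whole cause only if it was even across cell types. The mean of the fibroblast, macrophage and T cell lists, chosen after the data were seen, differed by 0.28 ± 1.06 (lower in 5 of 11 dogs). The gap was -1.82 ± 0.85 to the 3 lists, which were picked for their fall of -1.54 ± 0.56. The nerve list fell too (-1.73, lower in 10 of 11 dogs), as did the lymphatic list (-0.76, lower in 8 of 11). The fibroblast list alone differed by -0.18 (lower in 7 of 11) and the B cell list by 0.57 (lower in 4 of 11). A smaller share of only some of these cells was not tested as a cause of the 3 falls. Fat tissue with its vessels and mast cells in the gland specimens may account for them, but across the 11 dogs the adipocyte fall correlated weakly with the endothelial fall (r = 0.127, permutation p = 0.691, rho = 0.118, p = 0.734) and with the mast cell fall (r = 0.395, p = 0.229, rho = 0.545, p = 0.0880; adjusted over the 2 relations 0.691, 0.734, 0.458 and 0.176). Without the 2 dogs farthest from the median adipocyte fall r was 0.042 and 0.396. With the adipocyte covariate camera still called the endothelial list (adjusted p = 0.000219) and not the mast cell list (0.0920), but at no adipocyte change a straight line over the dogs gave -0.88 ± 0.50 and -1.25 ± 0.81 (SE, n = 11), within 2 SE of 0, so that this explanation stays open, as does a change in these cells in the carcinomas.

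Larger tumours tended to have lower levels of mitosis genes (r = -0.712 over 13 tumours, permutation p = 0.00660, rho = -0.649, p = 0.0183) and of DNA replication genes (r = -0.696, p = 0.00828, rho = -0.669, p = 0.0147). Chance stays open, because over all 48 relations computed between 24 lists and both size and survival the adjusted p was 0.199 for both lists (0.245 by rho). Without the 2 tumours farthest from the median size r was -0.512 and -0.480, and in the 9 tumours with the title suffix the mitosis list had r = -0.828 (permutation p = 0.00639) and rho = -0.861 (permutation p = 0.00441), falling to r = -0.467 without its 2 farthest tumours. More stroma and fewer tumour cells in larger tumours would lower the epithelial junction list too, but it had r = -0.0418 with size (permutation p = 0.891, rho = -0.208, p = 0.491) and the stromal list r = 0.299 (p = 0.320, rho = 0.296, p = 0.323), all with an adjusted p of 0.807 or more. The mitosis list minus the junction list had r = -0.485 (permutation p = 0.0923, rho = -0.493, p = 0.0873), which excludes neither this explanation nor a relation with size itself. Not followed up were the receptor tyrosine kinase list with size (rho = 0.652, permutation p = 0.0183) and the chaperone list with survival (rho = -0.670, permutation p = 0.0204). Both had the same adjusted p by rho as the mitosis list with size (0.245).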
